A study of Rattus norvegicus with 6 samples.

How the data were processed

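H3K27me3 chromatin immunoprecipitation libraries of neonatal rat cardiomyocytes were compared, 2 from cells given phosphate-buffered saline and 2 from cells given 5 mM α-KG for 24 h. Groups and replicate numbers were taken from the labels. The series also has 2 input samples, which were not analysed here. The deposited values are lists: the authors give, for each library, the Ensembl gene ID, gene symbol and protein domain names of every gene with a peak, with no header, no count, no score and no position. Whether an input was used to call peaks, how peaks were assigned to genes and whether duplicates were removed are not given in the sources used here. The submitters' processing notes name CASAVA, BWA, MACS2 and the rat genome build rn6, without roles or versions. Read depth is therefore unknown for every library, no confidence interval that needs it was computed, and a gene that is not listed may lack the mark or may have fallen below detection.

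The lists were read with Python 3.11.15 and pandas 2.3.3 and tested with numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6. Figures were drawn with matplotlib 3.10.9. A gene counted as lost when both control libraries and neither α-KG library listed it, and as gained in the reverse case. The number of listed genes was compared by an exact two-sided permutation test of the 4 libraries. Loss and gain were counted without a p-value and set beside the other 2 splits of the libraries and beside a log-linear model of the list lengths, in which each library and the number of libraries per gene had a term. Similarity was the Jaccard index.

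Gene lists, the tests and the rule for naming genes were fixed before the data were examined. The 22 lists hold 660 different genes, of which 590 had an entry in at least 1 library, 3 of them under an older symbol, and 10 genes had more than 1 ID. Entries, not symbols, were counted. List members were compared with other genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the lists. The background was the genes in both controls for loss, those in both α-KG libraries for gain, and those in any library for coverage, and lists with fewer than 3 members in the background were not tested. The adjusted threshold was 0.05. The rule names every list member lost or gained, 12 lost and 12 gained genes by rank, up to 4 members per list found in all 4 libraries, and a set of genes of interest for cardiac growth. Ranking was to use peak scores, and without scores it fell to alphabetical order by symbol. Some genes that the rule names are not reported here.

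After the data were examined, protein domains with at least 10 genes in the background were tested in the same way, and the nearness of lost genes to each other was tested with 10000 permutations of gene labels along the gene order of the RefSeq annotation of assembly GRCr8. That assembly differs from rn6, so it served only for names and gene order. A first match by current symbol left too few genes placed for the test to count, and the match was repeated with older symbols, which placed 86.5% of the lost genes with a symbol and 91.7% of the gained ones. The steps were run on simulated data. Changed genes were given the lost pattern itself, so recovering 200 of 200 among 22427 genes was fixed in advance and measures no sensitivity. Of 20 seeded lists, each of 40 genes with 12 changed ones placed in it, 20 were found. That share of changed genes is far above any in the fixed lists, where the highest was 1 lost of 14. The finding of all 20 therefore does not measure power for smaller changes. Of 200 random lists, 0 passed the adjusted threshold. With no change simulated, 292 genes were called lost and 525 gained. Simulated genes were drawn independently of each other, which neighbouring or related genes need not be.

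Alternatives tried were leaving out each library, a replicate block, other backgrounds, and genes with a symbol alone. Planned steps that need peak scores, positions, widths or read counts were not run, because the values used here are gene lists.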

Results

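Trimethylation of lysine 27 of histone H3 (H3K27me3), a mark that Polycomb proteins place on repressed genes, was profiled by chromatin immunoprecipitation and sequencing in primary cardiomyocytes of newborn rats. The cells had received phosphate-buffered saline (control) or 5 mM α-ketoglutarate (α-KG), a metabolite of the tricarboxylic acid (TCA) cycle and a cosubstrate of histone demethylases, for 24 h. Each group held 2 H3K27me3 libraries, called control 1, control 2, α-KG 1 and α-KG 2 below, and the 2 input samples were not used here. For each library the deposited values name the genes with a peak and nothing more, so a gene is either listed or not listed, and the strength, position and read depth behind a peak are unknown. The labels do not say that replicates were separate cultures, so every p-value measures only these libraries, and genes are not replicates.

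Genes that direct embryonic patterning were listed in nearly every library. All 102 entries on the list of developmental transcription factors, among them the neural determinant Atoh1 and the homeobox genes Barhl1 and Barhl2, were listed in all 4 libraries, against 62.6% of the other listed genes. The same held for 44 of 47 entries for Wnt, BMP, TGF-β and hedgehog ligands and their antagonists, with Bmp2, Bmp3, Bmp4 and Bmp6 as examples. It also held for 26 of 27 growth factor and regeneration genes, including the neuregulin receptors Erbb2, Erbb3 and Erbb4 and the matrix protein gene Agrn. Neuronal genes (34 of 39, with Cdh8, Cdh12, Csmd1 and Ctnna2) and Hox genes, which set position along the body axis (26 of 29, with Hoxb1, Hoxb2 and Hoxb13), were also listed in all 4 more often than other genes. Across the 22 gene lists fixed beforehand, two-sided Fisher's exact tests with Benjamini-Hochberg adjustment placed these 5 above other genes and 0 below them, and 8 lists had an unadjusted p under 0.05. The adjusted p was 6.87e-20 for developmental factors, 2.44e-05 for Wnt and BMP signalling, 0.00058 for growth factors, 0.00712 for neuronal genes and 0.0078 for Hox genes. The Hox call ended without control 1 (Fisher's exact adjusted p = 0.0543), and 10 of the 39 Hox genes on the list had no entry and so are not in its denominator. Glycolysis genes (10 of 25, adjusted p = 0.0709) and housekeeping genes (11 of 25, adjusted p = 0.125) had low shares that did not pass the adjusted Fisher's exact test. Glycolysis genes passed as lower without control 2 (Fisher's exact adjusted p = 0.0359), and 24 of the 25 on the list had an entry in any library, above the 69.0% of other RefSeq genes (adjusted p = 0.00455). Polycomb genes (25 of 30, Fisher's exact adjusted p = 0.0709) and JmjC or TET dioxygenases (21 of 25, 0.0997) had high shares that did not pass. Against all named RefSeq genes, both passed as higher (24 of 29 and 20 of 28, Fisher's exact adjusted p = 0.000216 and 0.0196). So did cell cycle inhibitors and cardiac transcription factors (16 of 20 each, Fisher's exact adjusted p = 0.00807) and fibroblast markers (16 of 22, 0.0361). RefSeq background genes were matched by current symbol only, whereas list members could also match by an older symbol. Renamed background genes count as not listed, so the RefSeq comparisons can overstate how far a list stands above other genes. Polycomb genes passed as higher without α-KG 2 (26 of 27, Fisher's exact adjusted p = 0.012) and imprinted genes without α-KG 1 (20 of 22, 0.0466). Neighbouring genes can share a peak, so Fisher p-values over genes are too small here and in the comparisons that follow. Gene length was not available, so the shares of the lists are not adjusted for it.

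The first comparison asked whether α-KG changed how many genes carried the mark. Control 1 listed 17245 genes, control 2 18442, α-KG 1 18120 and α-KG 2 19181. The group means were 17843.5 ± 846 genes for control and 18650.5 ± 750 for α-KG (SD, n = 2 each). The difference of 807 genes, or 4.52% of the control mean, was smaller than the difference of 1129 genes between the replicate 2 and replicate 1 means. It was 208.5 without control 1, 1405.5 without control 2, 1337.5 without α-KG 1 and 276.5 without α-KG 2. An exact two-sided permutation test gave p = 0.667, and 2 against 2 libraries cannot give less than 0.333. The libraries named 22427 genes together, of which 14077 (62.8%) were in all 4 and 2913 (13.0%) in 1. Of the 16005 genes listed in both controls, 88.0% were listed in both α-KG libraries.

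With all 4 libraries, those of the same treatment overlapped slightly more on average than those of different treatment, but not in every pair. The Jaccard index, the share of the combined genes of a pair of libraries that both list, was 0.813 for the controls and 0.775 for the α-KG libraries. Pairs of different treatment had 0.784 (control 1 with α-KG 1), 0.720 (control 1 with α-KG 2), 0.806 (control 2 with α-KG 1) and 0.762 (control 2 with α-KG 2). The pair of α-KG libraries thus lay below α-KG 1 paired with either control. The mean within groups exceeded the mean between groups by 0.0258, and without control 1 this difference was -0.00925. The 6 pairs share libraries, so no test was made.

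Loss of the mark under α-KG means a gene listed in both controls and in neither α-KG library. It reached few members of the fixed cardiac and cell cycle lists. At the overall share of 3.22%, lists this short would hold few lost members in any case, so they cannot show sparing. Ryr2, the calcium release channel of the sarcoplasmic reticulum, was lost, and it was the 1 member lost among the 20 sarcomere and calcium handling genes listed in both controls. Csmd3, on the neuronal list, and 1 of the 2 entries for the glycolytic enzyme gene Gapdh were the other list members lost. None of the G1/S genes (0 of 16), G2/M genes (0 of 11), cell cycle inhibitors (0 of 17), cardiac transcription factors (0 of 16) or growth factor genes (0 of 26) that both controls listed was lost. In all, 516 of 16005 genes (3.22%) were lost, 364 of them with a gene symbol. Fisher's exact tests found 0 of the 22 lists lost more or less often than other genes after adjustment, and 0 at an unadjusted p under 0.05. The files carry no score to rank genes by, so the lost genes named by rule are the first by symbol, and those reported here are 1100001G20Rik, 1700034J05Rik, 1700110M21Rik, 2700049A03Rik, 4930451C15Rik, 4930513O06Rik, 4933427G17Rik, 5830418K08Rik, 6820408C15Rik, AI462493 and the mitochondrial transporter gene Abcb8.

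Gain of the mark, the reverse pattern, reached at most 2 members of any fixed list, and no list was gained more often than other genes after adjustment. Kdm5a, a histone H3 lysine 4 demethylase, and Tet1, which oxidises methylated cytosine, were listed in both α-KG libraries and neither control. They were 2 of the 24 JmjC or TET dioxygenase entries in both α-KG libraries, with Fisher's exact unadjusted p = 0.292. Mef2c, a cardiac transcription factor, Cdc25b, a phosphatase that activates mitotic kinases, and Acadvl and Pfkfb2, enzymes of fatty acid oxidation and of glycolytic control, showed the same pattern. So did Mt2A (metallothionein), Psma1 (a proteasome subunit) and Tubb3 (neuronal β-tubulin). In all, 729 of the 16287 genes in both α-KG libraries (4.48%) were gained, 578 of them with a symbol. Fisher's exact tests found 0 of 22 lists past the adjusted threshold and 1 at an unadjusted p under 0.05. This was the developmental transcription factors, with 0 of 102 gained against 4.50% of other genes (Fisher's exact p = 0.0151, adjusted p = 0.333). All 102 were in all 4 libraries, so the absence of gain restates that listing. The first 12 gained genes by symbol were 1110001A16RIK, 1110058L19Rik, 1190007I07Rik, 3110082I17Rik, 4932443I19Rik, 6430531B16Rik, 9330160F10Rik, Aasdh, the drug efflux pump gene Abcb1a, the peroxisomal transporter gene Abcd2, the blood group gene Abo, and Acadvl.

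The counts of lost and gained genes depended on every library. Leaving out 1 library at a time gave 904 to 1369 lost genes and 1109 to 2290 gained genes, since fewer libraries then had to share the pattern. Among the 2544 genes listed in exactly 2 libraries, 48.9% divided by treatment, where equal splits would give 33.3%. The 3 ways of splitting the libraries into pairs gave 1245 genes for control against α-KG, 776 for replicate 1 against replicate 2, and 523 for the remaining split. With 3 splits no test can pass 0.05. A log-linear model of list lengths expected 278 lost and 570 gained genes, since the α-KG lists are longer, so the observed counts were 1.85 and 1.28 times expected. The model described the patterns poorly (deviance 1156 on 8 degrees of freedom).

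**Figure D1:**
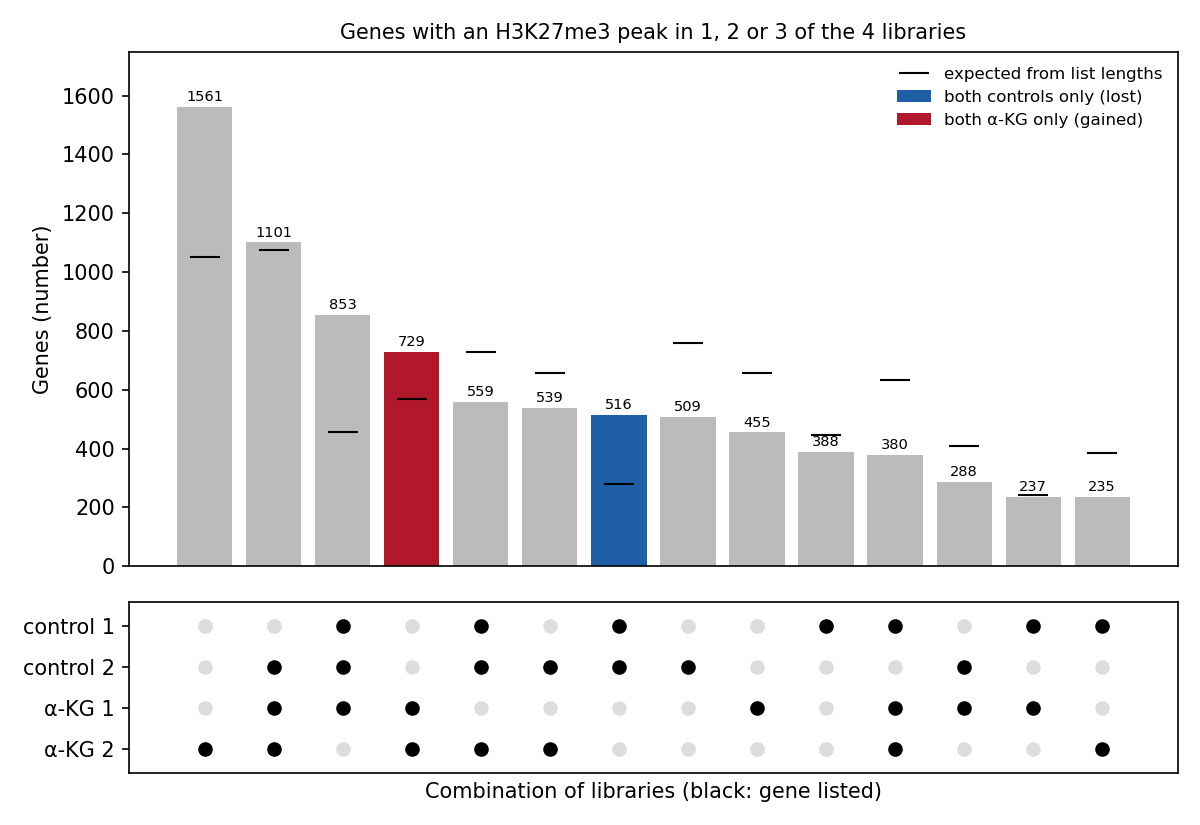
Number of genes (vertical axis) in each combination of the 4 libraries short of all 4, with black dots marking the libraries that list the gene and short lines the number expected from list lengths. Genes in both controls only number 516, genes in both α-KG libraries only number 729, and the tallest bar is the 1561 genes listed in α-KG 2 alone.

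Most genes named beforehand for their part in cardiac growth were listed in all 4 libraries, as were 62.8% of all genes listed in any library. Peak position and strength are unknown, so a listing does not show that such a gene was repressed. The H3K27 demethylase genes Kdm6a and Kdm6b, the methyltransferase gene Ezh2, the cyclin genes Ccnd1 and Ccnd2, the mitotic kinase gene Cdk1, and the inhibitor genes Cdkn1a, Cdkn2a and Cdkn2b were listed in all 4 libraries. So were Meis1, Nppb, Tnnt2, Gata4, Igf2 and the α-KG receptor gene Oxgr1. The natriuretic peptide gene Nppa was listed only in control 2, the myosin heavy chain gene Myh7 only in α-KG 2, and Myh6 had no entry.

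G1/S, G2/M and metabolic genes were listed most fully in α-KG 2, as were all genes together (19181 of 22427) and the cardiac factor, sarcomere, Polycomb, housekeeping and neuronal lists, and these are values without a test. For G1/S, G2/M, glycolysis and TCA cycle genes α-KG 1 stood within the range of the controls, and cell cycle inhibitors had 19 of 19 in both control 2 and α-KG 2. Of 23 G1/S entries, control 1, control 2 and α-KG 1 each listed 17 and α-KG 2 listed 23. The G2/M list had 14, 13, 14 and 19 of 21 entries in control 1, control 2, α-KG 1 and α-KG 2. In the same order, glycolysis genes had 16, 19, 16 and 22 of 25 entries and TCA cycle genes 25, 27, 25 and 30 of 33. The entries in α-KG 2 alone, named after their values were seen, were 5 of the 23 G1/S entries (Cdk2, Pcna, Mcm2, Mcm4 and Mcm5, which act in DNA replication) and 4 of the 21 G2/M entries (Cdc20, Aurkb, Bub1 and Top2a, which act in mitosis). In all 4 libraries were 16 G1/S entries, Mcm3 among them, and 10 G2/M entries, while Mcm6 and Ccnb1 were in control 1 and α-KG 2 and Kif11 in control 1 alone. Cardiac transcription factors had 16, 18, 19 and 20 of 20 entries, with Gata4, Gata5, Gata6 and Esrrg in all 4. Sarcomere genes had 22, 20, 21 and 23 of 26, with Actc1, Actn2, Atp2a2 and Casq2 in all 4.

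**Figure D2:**
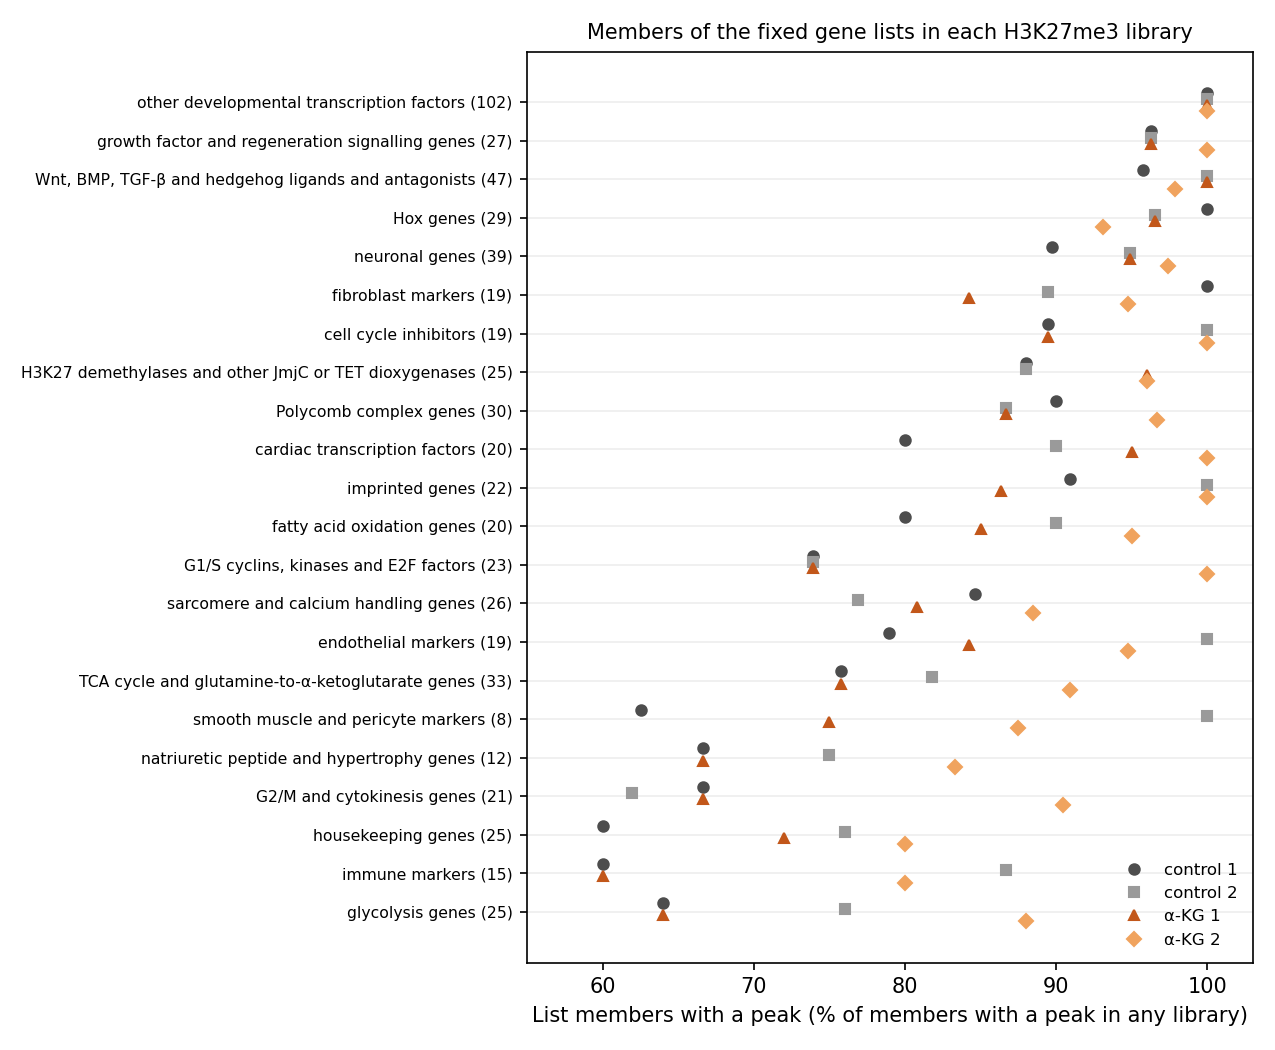
Entries of each of the 22 gene lists that have a peak in each library, in percent of the entries with a peak in any library (horizontal axis), with the number of entries in brackets and 1 point per library. Developmental transcription factors are listed at 102 of 102 in each library, and for G1/S genes α-KG 2 lists 23 entries against 17 in each of the others.

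The remaining lists are given as counts without a test. In the order control 1, control 2, α-KG 1 and α-KG 2, cell cycle inhibitors had 17, 19, 17 and 19 of 19 entries, and natriuretic peptide and hypertrophy genes 8, 9, 8 and 10 of 12. The JmjC and TET dioxygenases had 22, 22, 24 and 24 of 25, Polycomb genes 27, 26, 26 and 29 of 30, fatty acid oxidation genes 16, 18, 17 and 19 of 20, and imprinted genes 20, 22, 19 and 22 of 22. Housekeeping genes had 15, 19, 18 and 20 of 25. Among markers of other cell types, fibroblast genes had 19, 17, 16 and 18 of 19 entries, endothelial genes 15, 19, 16 and 18 of 19, smooth muscle and pericyte genes 5, 8, 6 and 7 of 8, and immune genes 9, 13, 9 and 12 of 15. A peak at such a marker does not show which cells carried it.

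Receptor families with many copies in the genome made up an outsized part of the lost genes. Olfactory receptor genes, which encode odorant receptors of the nose, were lost in 73 of 347 cases (21.0%) against 2.65% of other genes with a protein domain, and without α-KG 1 in 177 of 347 (51.0%). They were also gained in 20 of 203 cases (9.85% against 4.46%; Fisher's exact p = 0.00101, adjusted p = 0.0977), which did not pass. Against genes listed in any library their gained share was lower than that of others, 20 of 725 (2.76% against 3.33%). The gained share was 42 of 203 (20.7% against 6.61%) without control 1 and 83 of 443 (18.7% against 6.17%) without α-KG 2. It was 34 of 203 (16.7% against 11.5%) without control 2 and 46 of 274 (16.8% against 12.2%) without α-KG 1. Type 1 vomeronasal receptors, which sense pheromones, were lost in 10 of 53 cases (18.9%) and C-type lectin genes in 12 of 73 (16.4%). Without α-KG 1 the vomeronasal loss was 27 of 53 (50.9% against 8.05% of others) and the lectin loss 18 of 73 (24.7% against 8.14%). Without α-KG 2 the vomeronasal loss was 11 of 53 (20.8% against 6.52%) and the lectin loss 17 of 73 (23.3% against 6.48%). In that setting 4 of 57 vomeronasal genes were gained (7.02% against 6.56%). Of the lectin genes, 3 of 75 were gained there, a lower share than the 6.58% of others. Control 1, control 2, α-KG 1 and α-KG 2 listed 67, 58, 57 and 34 of 79 vomeronasal receptor genes, so these too were fewest in α-KG 2. In the same order they listed 88, 87, 75 and 66 of 107 C-type lectin genes, so both α-KG libraries lay below both controls. The lectin genes, named after their values were seen, included the natural killer cell receptor genes Klra17, Klrb1a, Klrc1, Klre1 and Klrk1. Genes with the immunoglobulin V-set subgroup domain were both lost (17 of 123) and gained (17 of 108) more often than others, but the gain did not pass without α-KG 1 (Fisher's exact adjusted p = 0.273) or against genes listed in any library (adjusted p = 0.597). Homeobox genes, a family of transcription factors, were lost in 0 of 203 cases (Fisher's exact adjusted p = 0.175), and their lower loss passed without control 1, control 2 or α-KG 1 (adjusted p = 0.0126, 0.00264 and 0.00182) but not without α-KG 2 (0.131). Homeobox genes were gained in 2 of 203 cases (Fisher's exact adjusted p = 0.407), and their lower gain passed without control 2, α-KG 1 or α-KG 2 (adjusted p = 0.0025, 0.0019 and 0.0271). Since 196 of 225 homeobox genes were in all 4 libraries, their lower loss and lower gain largely restate that listing. The domain tests were added after the data were seen. By Fisher's exact test with Benjamini-Hochberg adjustment, 10 of 665 domains were lost more often than others, and 1 of 674, the V-set subgroup, was gained more often. Several of the 10 share genes, so they are not 10 separate families. Klra17, for example, counts under the C-type lectin domain and under another of the 10. The adjusted p for loss was 3.16e-37 for olfactory receptors, 0.000499 for vomeronasal receptors, 0.000308 for C-type lectins and 4.25e-05 for the V-set subgroup, whose gain had 0.00466. Per library, control 1, control 2, α-KG 1 and α-KG 2 listed 497, 466, 443 and 274 of 725 olfactory receptor genes, so α-KG 2 had the fewest. Reads and peaks of near-identical copies can be split between genes, which makes the state of single family members uncertain.

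**Figure D3:**
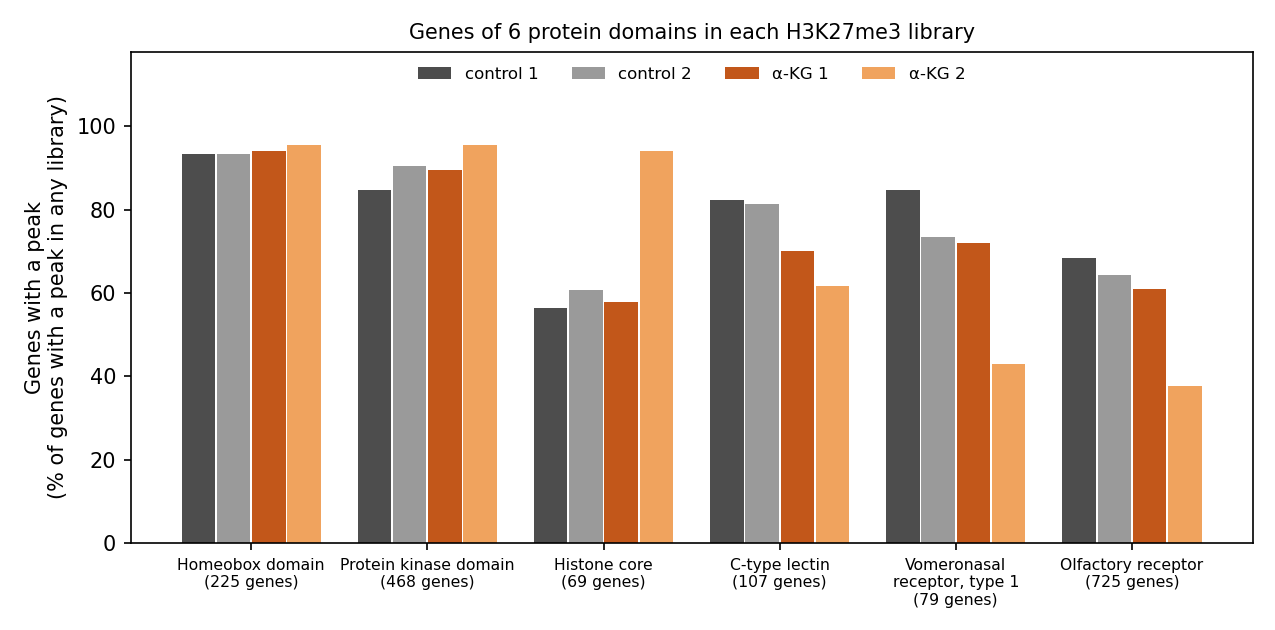
Genes of 6 protein domains with a peak in each library, in percent of the genes of that domain with a peak in any library (vertical axis), with bars for control 1, control 2, α-KG 1 and α-KG 2. Olfactory receptor genes fall to 274 of 725 in α-KG 2, while core histone genes reach 65 of 69 there against 39, 42 and 40 in the other libraries.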

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

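The settings for domains, olfactory receptors, similarity and list coverage, and the count of listed genes with a symbol, were chosen after the data were seen. The difference in listed genes stayed positive, from 208.5 to 1405.5 without 1 library and 836.5 for genes with a symbol. Without 1 library, lost genes numbered 904 to 1369 and gained genes 1109 to 2290, by construction, and each of the 4 libraries moved at least 1 of these counts by over 1.5 times. The excess of similarity within groups ranged from -0.00925 without control 1, a reversal, to 0.0718 without α-KG 1; the cause was not tested. Lists past the threshold numbered 0 to 1 for loss and 1 to 1 for gain, each time the developmental factors with 0 of 102 changed, and 4 to 6 for coverage. All 102 were in all 4 libraries, so 0 changed was fixed whichever library was left out. Those loss and gain calls only restate that listing. Coverage rose to 10 lists against all named RefSeq genes, where renamed background genes count as not listed, so the rise can be partly one of naming. With that background it was 11 when a gene needed listing in any library only, and Hox genes did not pass there (29 of 39, Fisher's exact adjusted p = 0.664). Domains numbered 15 to 34 for loss (19 without control 2, 34 without α-KG 1) and 6 to 21 for gain (14, 6, 17 and 21 without control 1, control 2, α-KG 1 and α-KG 2). Gain fell to 0 domains with the background of genes in any library. Olfactory receptor loss was 27.7% to 51.0% without 1 library, the highest without α-KG 1. With the background of genes in any library it was 73 of 725 (10.1% against 1.91% of others). Over genes, the listing in replicate 1 minus that in replicate 2 correlated at 0.0478 between control and α-KG. Replicate 2 listed more genes than replicate 1 in both groups. With this low correlation and only 2 same-numbered pairs, the replicate numbers are not taken to pair the samples. With a replicate block the difference was 807 genes (exact sign-flip p = 0.5, the smallest 2 pairs can give); pair 1 alone had 1698 lost and 2573 gained genes, pair 2 alone 2166 and 2905, and both pairs together 516 and 729 by construction. Not run, for want of scores, positions or counts, were the stricter score threshold, equal peak numbers, promoter peaks, gene bodies by coordinates, peak overlap, peak strength and width, and the count test. Unknown depth limits every absence.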

Other observations

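All tests in this part were chosen after the result was seen. All 35 listed voltage-dependent potassium channel genes and 59 of 61 genes with the domain of two-pore potassium channels, which set resting potential, were in all 4 libraries. Homeobox genes were in all 4 in 196 of 225 cases and protein kinase genes in 375 of 468. Rhodopsin-like G protein-coupled receptors, a class that takes in odorant receptors, stood lower, with 361 of 1068 in all 4, and olfactory receptor genes had 147 of 725. By Fisher's exact test with Benjamini-Hochberg adjustment, 90 of 868 domains were in all 4 libraries more often than other genes and 35 less often. Domains can share genes, so these counts are not of separate families. Gene length was not available, so these shares are not adjusted for it.

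Whether α-KG 2 alone gives the net loss of olfactory receptor genes stays open, since without it they were both lost (27.7% against 5.97% of others, Fisher's exact adjusted p = 9.99e-33) and gained (18.7% against 6.17%, adjusted p = 9.00e-16) more often than other genes. They do not come and go evenly between any libraries, since they made up 146 of the 1041 genes listed only in a pair of libraries without α-KG 2 and 42 of the 1503 listed only in a pair with it (Fisher's exact p = 2.79e-26). Among genes absent from α-KG 2, they made up 73 of the 516 listed only in both controls and 73 of the 525 listed only in 1 control and α-KG 1, an odds ratio of 1.02 (95% interval 0.708 to 1.47; Fisher's exact p = 0.929). This is consistent with turnover between control 1, control 2 and α-KG 1, joined to low listing in α-KG 2, though the interval leaves room for a moderate difference. An effect of α-KG stays open, as does base composition, which was not tested.

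Listing raised evenly in every class of gene would not explain why α-KG 2 lists the most genes. That library listed 274 olfactory receptor genes, fewer than each other library (exact McNemar p = 5.63e-34, 2.67e-25 and 1.32e-22 against control 1, control 2 and α-KG 1). These p-values treat near-identical family members as independent and are too small. Read depth is unknown, so a depth difference that acts unevenly on gene classes is not excluded. G1/S, G2/M, housekeeping, glycolysis and TCA genes were listed in α-KG 2 alone in 19 of 125 cases (15.2%) against 6.91% of other genes (Fisher's exact p = 0.00115). Cell cycle inhibitors and fatty acid oxidation genes, which are not among the 125, had 0 of 19 and 0 of 20 entries in α-KG 2 alone. Other lists outside the 125 had more: natriuretic peptide and hypertrophy genes 2 of 12, immune genes 2 of 15, sarcomere genes 3 of 26 and Polycomb genes 3 of 30. Cardiac transcription factors had 1 of 20, growth factor genes 1 of 27 and neuronal genes 1 of 39, and the rest had 0. Per library, α-KG 1 listed 89 of the 125 entries, between the 85 and 93 of the controls, and α-KG 2 listed 114. The 5 lists that make up the 125 were picked because their values had been seen. These values therefore decide neither whether peaks at active genes may account for the longer list nor whether α-KG acted in both libraries. Both stay open, as does a bias in that library toward some base compositions.

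The genes that divide by treatment were 1.47 times the number expected from list lengths, where the other 2 splits gave 0.863 and 0.656 times. With 3 splits no share under 0.05 can be reached. The excess cannot be told apart from uneven calling, because the model described the patterns poorly: the 12 other single combinations ranged from 0.601 to 1.87 times expected. The 2 inputs, 1 per treatment, also separate with the treatment, and an effect of α-KG stays open.

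Lost genes lay next to each other in 24 adjacent pairs, against 8.67 for permuted labels (one-sided permutation p = 0.0001, the smallest that the permutations can give). Broad regions that change together may account for this, as a hypothesis only. Without olfactory receptor genes there were 13 pairs against 5.66 (permutation p = 0.0056), and gained genes had 41 against 23.6 (p = 0.0007). Vomeronasal receptor and C-type lectin genes, also lost more often than others, stayed among the 13 pairs' candidates. Whether such families supply the remaining excess was not tested. Among olfactory receptor genes alone, lost ones formed 12 pairs against 12.9 (permutation p = 0.679). A peak assigned to several neighbouring genes would give the same pattern, and this was not tested.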
